A study of Mus musculus with 2 samples.

How the data were processed

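MicroRNA-seq libraries were prepared from total RNA of adrenal gland tissue of C57BL/6J mice, with a size range below 30 (taken as nt) per the labels. The series holds 2 libraries in 1 group, which the labels number as biological replicates 1 and 2, each with technical replicate 1. The labels give each library its own tissue sample and the same donor identifier. They do not say in so many words that the tissue came from separate animals, so the p-values describe only these libraries, and their differences may be technical. One label calls the animals female, and another says that sex was not collected.

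For each library the authors deposited a table of raw read counts for 2202 microRNA genes, made on the mm10 assembly with the GENCODE M21 annotation per the description deposited beside the tables. The labels' protocols point to adapter trimming. The aligner, the counting tool and their settings are not given in the sources used here. Each table holds 3 columns of counts with no header, read from their values and layout as reads on either strand, on the strand of the gene and on the opposite strand. By a rule set before the data were examined, the stranded column with the larger total over genes was taken as the strand of the gene, since the description does not name it. The first 4 rows of each table name no gene and count unmapped reads, reads with several alignments, reads outside the annotated genes and ambiguous reads. They were left out of the library sizes. Reads with several alignments stand in their own row, apart from the genes, so a microRNA made from several near-identical loci can be under-counted at each of them. A count is for a whole hairpin gene, so the mature products of its arms are not told apart. The libraries carry no stated molecular identifiers, so intervals and detection limits cover counting error only.

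All 2202 identifiers matched the GENCODE M21 annotation, which gave symbols, mm10 coordinates and overlapping genes. Hairpin sequences came from the transcripts of the same release. CPM values are the deposited counts on the strand of the gene per 1000000 counts of each library's total over genes. A gene was called detected at 10 counts or more. A count of 0 allows up to 3 counts.

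With 1 group there is no contrast between conditions. The only comparison between samples is of the 2 libraries with each other. Each gene with at least 20 counts over both libraries was tested with an exact two-sided binomial test of its counts against the ratio of the library sizes scaled by TMM (edgeR 4.0.16, R 4.3.3). The p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. This test compares 2 libraries and knows counting error only. It says nothing about conditions or about animals in general. Log2 ratios are given as replicate 2 over replicate 1, with 0.5 counts added to each library, and with an exact (Clopper-Pearson) 95% counting interval. TMM lowered all log2 ratios by 0.10 against scaling by total counts. The spread between replicates was estimated as edgeR's common dispersion in a model with an intercept only. Its interval came from 100 resamplings of genes, fitted with another edgeR estimator of the common dispersion. It covers variation over genes and not over libraries. Pearson and Spearman correlations of log2(CPM + 1) were taken across genes, which are not independent replicates, with intervals from 1000 resamplings.

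Gene lists were fixed before the data were examined. The 25 lists hold microRNA families, microRNAs typical of other cell types (endothelial, fibroblast and smooth muscle, erythroid, leukocyte, striated muscle, liver, kidney, epithelial, neural and neuroendocrine), genomic clusters, microRNAs studied in steroid-producing cells, and microRNA genes that resemble other RNA classes. Some genes belong to more than one list. For lists with at least 3 tested genes, the median log2 ratio was placed among 10000 random lists of the same size matched on deciles of mean CPM. That percentile describes these libraries and is not a p-value. The genes named are the 15 with the highest mean CPM, the 5 with the largest log2 ratio in each direction among called genes with a mean of at least 100 CPM, the leading 3 of each list, and the 3 with the most antisense counts. Genes named outside this rule are said to be so. Genes in 28 sets of loci with near-identical mature sequences were marked in advance.

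The binomial test was tested on simulated Poisson counts with the library sizes given, over 426 tested genes, with known changes in genes drawn at random. It called 86.96% of the genes simulated at a fold of 0.5, 82.61% at 0.667, 64% at 1.5 and 94% at 2, all in the right direction, and 1 of 234 unchanged genes. The dispersion fit returned 0.104, 0.305 and 0.494 for simulated coefficients of variation of 0.1, 0.3 and 0.5. Counts were simulated for 2202 genes, and only genes with at least 20 simulated counts over both libraries were fitted. A simulated list shifted by 1 on the log2 scale lay at percentile 99.5, and 7 of 100 unshifted lists lay in the outer 5%. Alternatives were DESeq2 1.42.0 size factors, total counts, other count minimums, the counts on either strand, other denominators, other pseudocounts, thinning of the deeper library and each library alone. The remaining computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Signal tracks and alignments of the series were not used here.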

Results

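MicroRNA levels were measured in the adrenal gland, the paired endocrine organ whose cortex makes steroid hormones and whose medulla makes catecholamines, in 2 libraries from C57BL/6J mice. The replicate 1 library held 18743064 reads, of which 9137907 (48.8%) were counted on the strand of a microRNA gene. The replicate 2 library held 14457994 reads with 6570375 (45.4%) counted. Reads with several alignments made up 35.9% and 36.0% of the libraries, unmapped reads 11.7% and 13.7%, and reads outside microRNA genes 3.72% and 4.83%. At these depths a gene with a count of 0 lies below 0.328 CPM in replicate 1 and below 0.457 CPM in replicate 2. This bound covers counting error only. It does not hold for genes with reads that align to several loci, since those reads are not in the gene counts.

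Of 2202 microRNA genes, 403 had at least 10 counts in both libraries, and 1384 had none in either. Replicate 1 had 441 such genes and replicate 2 had 418. The counted pool was concentrated in few genes. Reads with several alignments are not in these counts. The shares and ranks therefore leave out such reads of genes with near-identical copies. The leading gene of each library held 11.3% ± 0.986 of the counts (SD, n = 2), the leading 5 held 36.6% ± 1.47, the leading 10 held 58.9% ± 3.10 and the leading 20 held 77.1% ± 1.53. In the abundance classes, 21 genes at or above 10000 CPM held 78.1% of the counts, 54 genes between 1000 and 10000 CPM held 17.3%, and 109 genes between 100 and 1000 CPM held 4.16%. The libraries shared 9 of their 10 most abundant genes and 19 of their 20.

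The most abundant gene in these counts was Mirlet7g, at 112919 ± 9863 CPM (SD, n = 2). It lies on chromosome 9 at 106178840-106178927 (mm10, plus strand) in an intron of Wdr82. Mirlet7b, on chromosome 15 at 85707319-85707403, followed at 84252 ± 3461 CPM. Both belong to the let-7 family, whose members are widely expressed in differentiated tissue. Mir126a, the endothelial microRNA on chromosome 2 at 26591357-26591429 within Egfl7, followed at 58001 ± 5199 CPM, ahead of Mir23b (chromosome 13, 63300484-63300557) at 55295 ± 3888 CPM and Mir10a (chromosome 11, 96317165-96317274) at 54938 ± 2159 CPM. The means of Mir23b and Mir10a lay within 1 SD of that of Mir126a. Mir375, known from pancreatic islets and other neuroendocrine cells, lies on chromosome 1 at 74900658-74900721 outside other annotated genes and reached 49445 ± 1171 CPM. Mir139, in an intron of the phosphodiesterase gene Pde2a on chromosome 7 (101475376-101475443), reached 47532 ± 1141 CPM.

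Among the other leading genes, Mirlet7d had 42986 ± 4473 CPM, Mir23a 42105 ± 18657 CPM, Mirlet7i 37613 ± 415 CPM and Mir22 31062 ± 8741 CPM. Mir99a had 22390 ± 3590 CPM, Mir26b 21281 ± 4599 CPM, Mir21a 19171 ± 14292 CPM and Mir127 17704 ± 2768 CPM. Mir21a overlaps an exon of Vmp1 on chromosome 11 (86584067-86584158), and Mir127 lies opposite an exon of Rtl1 on chromosome 12 (109592846-109592915). The SDs of Mir23a and Mir21a were large because the libraries differed, as described with the comparison of the libraries.

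**Figure D1:**
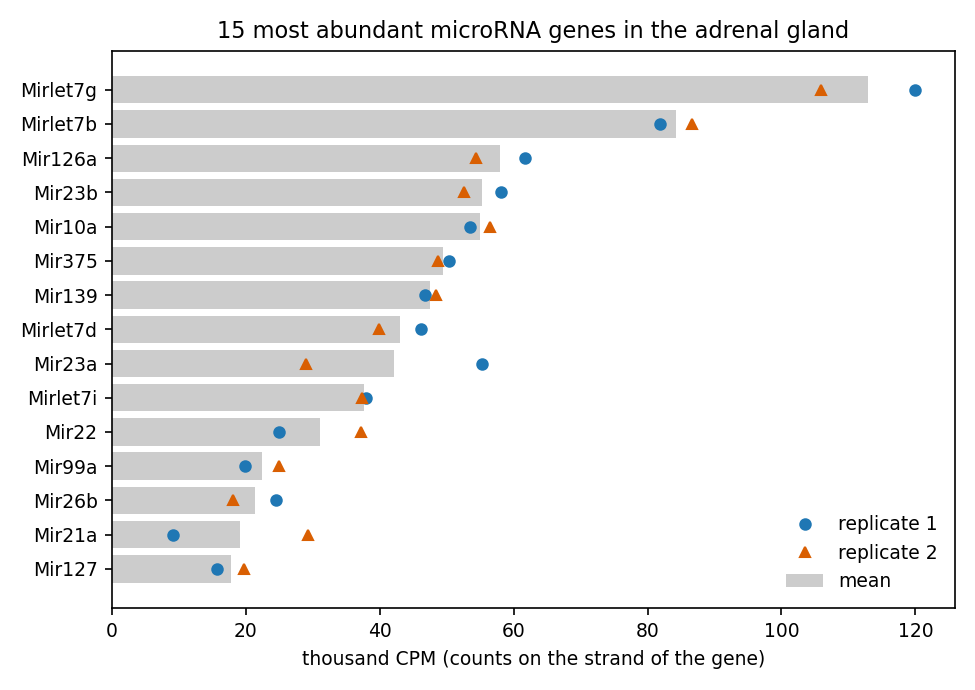
Level of the 15 most abundant microRNA genes in CPM (axis in units of 1000), with the mean as a bar and each library as a point. Mirlet7g leads at a mean of 112919 CPM, and Mir23a and Mir21a show the widest gap between the libraries.

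The families differed widely in abundance. The let-7 family held 31.2% ± 1.09 of all counts, and all 12 of its genes had at least 10 counts in both libraries. The miR-10/99/100 family held 10.3% ± 0.688, led by Mir10a, Mir99a and Mir10b, the last at 16918 ± 2092 CPM in introns of Hoxd3 and Hoxd4. The miR-26 family held 2.14% ± 0.443, nearly all of it from Mir26b in an intron of Ctdsp1. The miR-30 family held 1.85% ± 0.386, with Mir30d at 7548 ± 4997 CPM, Mir30a at 5595 ± 1058 CPM and Mir30e at 4828 ± 2211 CPM. The miR-15/16 family held 1.48% ± 0.231, with Mir322 at 8548 ± 1324 CPM, Mir15a at 1798 ± 1255 CPM and Mir195a at 1498 ± 35.8 CPM. The family of miR-34 and miR-449 held 0.737% ± 0.0818, from Mir34a (3653 ± 645 CPM), Mir34c (3587 ± 175 CPM) and Mir34b (88.6 ± 0.676 CPM). The miR-29 family held 0.702% ± 0.0597, led by Mir29a at 6142 ± 588 CPM, ahead of Mir29c at 789 ± 12.0 CPM and Mir29b-1 at 63.5 ± 1.16 CPM. The miR-181 family held 0.166% ± 0.00866, from Mir181d (730 ± 61.1 CPM), Mir181c (695 ± 62.9 CPM) and Mir181b-2 (156 ± 19.5 CPM). Genes with near-identical copies elsewhere in the genome, such as Mir26a-1, Mir26a-2, Mir29b-1, Mir181b-2, Mir92-1 and Mir194-2, are uncertain, because reads with several alignments are not in the gene counts.

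MicroRNAs studied in steroid-producing cells were all detected, 24 of 24, and held 5.02% ± 1.44 of the counts. Their leading members were Mir21a, Mir125a at 12968 ± 541 CPM and Mir34a. Of the 24 genes, 6 are multi-copy genes whose reads with several alignments are left out, so their ranks and the share are uncertain. The list overlaps other lists and was assembled from general knowledge, so its share does not measure the cortex. The neural and neuroendocrine list held a similar share, 5.63% ± 0.229, of which Mir375 was the main part. Mir7b (3109 ± 390 CPM) and Mir149 (2521 ± 544 CPM, in an intron of Gpc1) followed. Of that list's 23 genes, 15 had at least 10 counts in both libraries and 6 had none in either. The genes at 0 include Mir9-1 and Mir124a-1, named after their values were seen. Each has near-identical copies, so its level cannot be read from these counts.

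The other cell-type lists ranged over several orders of magnitude. The endothelial list held 6.17% and 5.43% in the libraries, which was nearly all Mir126a, since its opposite-strand partner Mir126b had 17 and 3 counts. The fibroblast and smooth muscle list held 1.70% ± 0.274, from Mir143 (14230 ± 2163 CPM), Mir214 (1648 ± 729 CPM) and Mir145a (1081 ± 147 CPM). The leukocyte list held 0.340% ± 0.0228, from Mir146 (11399 and 9172 counts), Mir342 (829 ± 224 CPM) and Mir150 (431 ± 89.1 CPM). The epithelial list held 0.0735% ± 0.000948, nearly all from Mir203 (683 ± 7.13 CPM), while Mir200c had 20.2 ± 0.970 CPM and Mir200b 16.3 ± 5.12 CPM. The erythroid list held 0.0219% ± 0.0107, led by Mir451a at 177 ± 95.7 CPM, with Mir144 at 193 and 163 counts and Mir486 at 19.1 ± 8.29 CPM. The kidney list, of interest because the gland lies on the kidney, held 0.0115% ± 0.000418, with Mir204 at 47.9 ± 9.17 CPM, Mir192 at 35.0 ± 3.17 CPM and Mir194-2 at 31.7 ± 1.40 CPM. Mir122, the abundant microRNA of hepatocytes, had 99.8 ± 40.0 CPM. The striated muscle list summed to 5.88 ± 0.728 CPM, from Mir1b (4.38 ± 0.473 CPM), Mir499 (1.05 ± 0.242 CPM) and Mir206 (2 and 3 counts), and 6 of its 10 genes had no count. Mir1a-1 and Mir133a-1, named after their values were seen, were at 0 in both libraries, but each has an identical copy, so their level cannot be read from these counts.

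**Figure D2:**
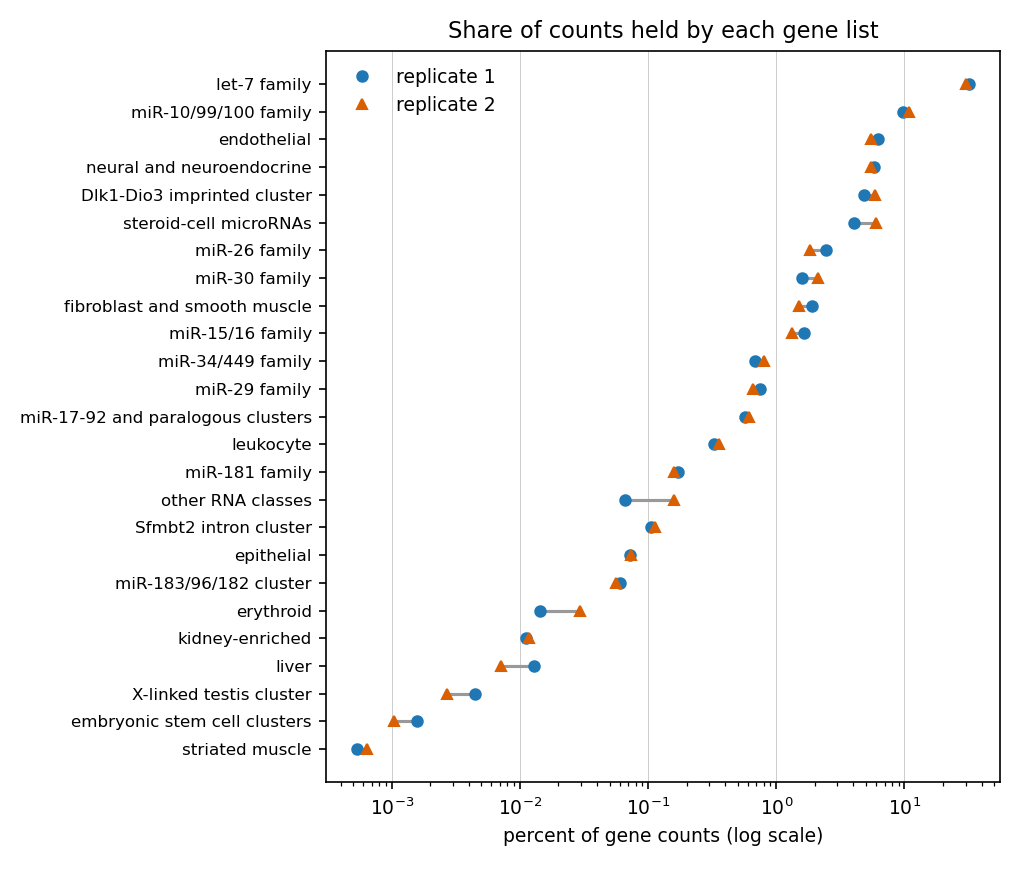
Percent of gene counts held by each gene list on a log scale, 1 point per library with a line between them. Shares run from 31.2% for the let-7 family to below 0.001% for striated muscle, and most lists differ far more from each other than between the libraries. In the striated muscle list, 4 of 10 genes are multi-copy genes whose level cannot be read from these counts.

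The imprinted Dlk1-Dio3 region on chromosome 12, whose microRNAs are transcribed from the maternal chromosome, was broadly expressed. Its list held 5.34% ± 0.706 of the counts, and 48 of its 56 genes had at least 10 counts in both libraries. Mir127, Mir411 (7103 ± 570 CPM) and Mir379 (6149 ± 2006 CPM) led it. The miR-17-92 cluster and its paralogues held 0.590% ± 0.0245, with Mir93 at 1637 ± 127 CPM overlapping an exon of Mcm7, Mir17 at 1591 ± 18.8 CPM and Mir92-1 at 1083 ± 184 CPM. Genes named Mir297, Mir466, Mir467 and Mir669 with their suffixes, most of which belong to the rodent cluster in an intron of Sfmbt2, held 0.109% ± 0.00549, but 8 of these 80 genes reached 10 counts in both libraries and 68 had none, and many are near-copies of each other. The leading genes were Mir467d (433 ± 34.4 CPM), Mir467e (211 ± 13.6 CPM) and Mir669o (137 ± 14.6 CPM). The cluster of Mir183, Mir96 and Mir182 held 0.0579% ± 0.00286, with Mir182 at 323 ± 45.0 CPM, Mir183 at 238 ± 30.3 CPM and Mir96 at 252 and 51 counts. Low summed levels were found for the X-linked cluster known from testis (36.0 ± 12.4 CPM in all, with Mir547 at 24.4 ± 15.6 CPM, Mir201 at 10.9 ± 2.62 CPM and Mir741 at 0 and 4 counts) and the embryonic stem cell clusters (13.1 ± 3.72 CPM in all, with Mir302d at 2.88 ± 0.415 CPM, Mir302a at 2.41 ± 1.69 CPM and Mir294 at 2.34 ± 0.720 CPM). Annotated microRNA genes listed beforehand as resembling other RNA classes held 0.113% ± 0.0661, led by Mir1839 (943 ± 626 CPM, within a scaRNA gene), Mir664 (131 ± 25.5 CPM, within Snora36b) and Mir6236 (21.5 ± 6.78 CPM).

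The comparison of the libraries asks how far 2 adrenal samples of the same strain differ. Mir21a, a broadly expressed microRNA, was 3.01-fold higher in replicate 2 (log2 ratio 1.59, 95% counting interval 1.58 to 1.60). Mir674 was 4.03-fold higher in replicate 2, at 14920 and 46450 counts. Mir31 and Snord43, the latter annotated as a microRNA gene in an intron of Rpl3, were 2.80-fold and 2.92-fold higher there. Mir26a-2 had 106 and 1655 counts, a 20.1-fold difference, but its mature sequence has an identical copy. In the other direction Mir185, in an intron of Tango2, had 7853 and 899 counts, a log2 ratio of -2.75 (interval -2.85 to -2.65). Mir15a (-1.66), Mir497 (-1.30), Mir222 (-1.22) and Mir30e (-1.07) were also higher in replicate 1. Among the most abundant genes Mir23a had a log2 ratio of -1.04, Mir26b of -0.55 and Mir22 of 0.48, while Mir375 had -0.15 and Mirlet7i -0.13.

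In all, 239 of 426 tested genes differed beyond counting error (exact two-sided binomial test with Benjamini-Hochberg adjustment, adjusted p under 0.05), 110 higher in replicate 2 and 129 higher in replicate 1. Scaled by total counts in place of TMM, 243 differed, with 150 higher in replicate 2 and 93 higher in replicate 1, so the split between directions depends on the scaling. At an unadjusted p under 0.05 there were 255 genes. Of the called genes 46 differed by more than 2-fold, 24 higher in replicate 2 and 22 in replicate 1. Called genes made up 158 of the 184 genes at or above a mean of 100 CPM, where counting error is small, but 150 of those 184 lay within 1.5-fold. Against counting error alone, the likelihood-ratio chi-square over genes was 373428 with 425 degrees of freedom, so the libraries were not counted as repeated deposits of a single library. It does not tell a difference between tissues from one between preparations. The common biological coefficient of variation from edgeR was 0.299 (interval over resampled genes 0.267 to 0.345). The median absolute log2 ratio was 0.29 (interval 0.26 to 0.33), a 1.23-fold difference, and 0.52 with no filter on low counts. Across genes, log2(CPM + 1) correlated with Pearson's r = 0.987 and Spearman's rho = 0.980, and with no filter r was 0.992 and rho 0.930. With 2 libraries of the same group, none of these differences can be assigned to a condition, and no test across animals is possible.

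**Figure D3:**
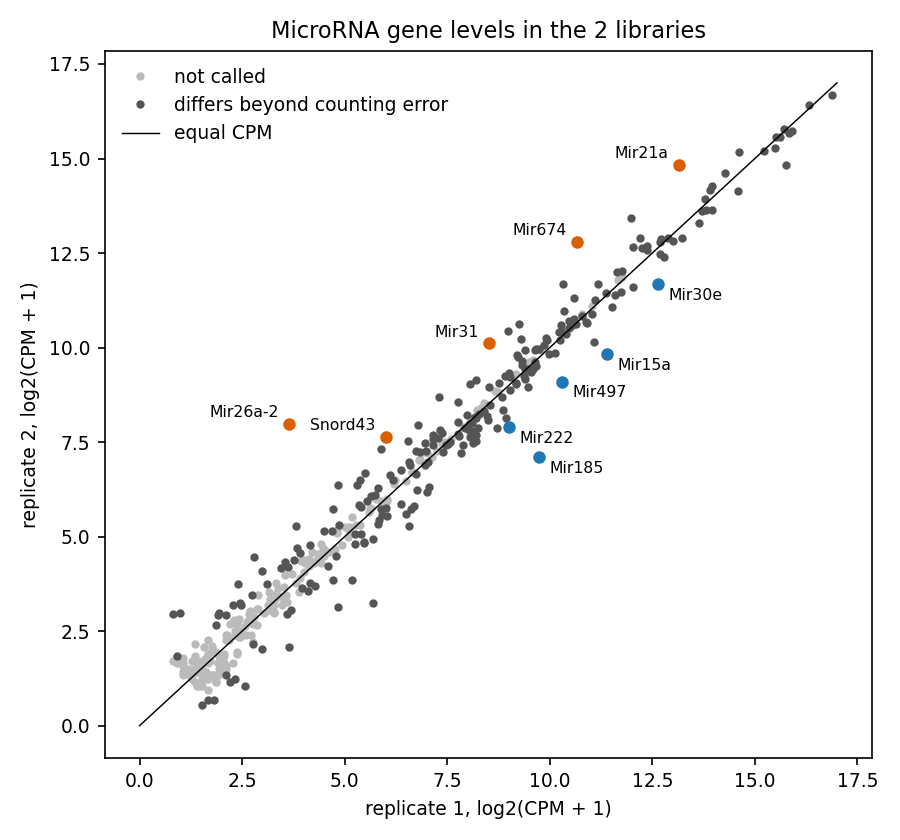
Level of each tested gene in replicate 1 and replicate 2 as log2(CPM + 1), with the line of equal CPM. Most genes lie near the line, and the 5 named genes with the largest ratio in each direction are coloured.

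The neural and neuroendocrine list had a median log2 ratio of -0.36, at percentile 0.72 of random lists. Of its 15 tested genes 10 were higher in replicate 1, none was higher in replicate 2 and 5 did not pass (10 adjusted over the list alone). Without the filter on low counts its percentile was 6.37, and 9 of the 15 are multi-copy genes whose counts are uncertain. Copies with near-identical mature sequences are not separate observations. The percentile and the split between directions count each copy as a gene of its own, so both may overstate the shift. Mir375 (-0.15), Mir7b (-0.36) and Mir149 (-0.55) were among the 10. Scaled by total counts, 7 were higher in replicate 1 and 1 in replicate 2. The erythroid list had a median of 0.81, at percentile 98.7, with Mir451a (1.06) and Mir486 (0.81) higher in replicate 2 and Mir144 at 0.13 (interval -0.18 to 0.44). With 3 tested genes, this median is the ratio of Mir486 alone, at 121 and 164 counts. Mir486 overlaps Mir3107 on the opposite strand, and whether it loses reads with several alignments was not tested. The miR-26 family, with a median of 1.14 where the middle 95% of random lists ran from -0.53 to 0.82, rests on the multi-copy genes Mir26a-1 and Mir26a-2, while its abundant member Mir26b was higher in replicate 1. These were the 3 lists of 21 outside the middle 95% of random lists. Chance would place 1.05 there if genes shifted independently of each other. In the counts on either strand the erythroid list had 1 tested gene and no percentile. The miR-15/16 family lay outside there, at percentile 98.6 with a median of 0.40, over 7 tested genes in place of 8. Mir451a, Mir486 and Mir497, which each overlap a microRNA gene on the opposite strand, had no counts in that column.

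The other lists with at least 3 tested genes lay inside those bounds, although many of their members differed in both directions. The 5 tested genes of the embryonic stem cell clusters had a median of -0.71 (random lists -0.91 to 0.59), with 1 higher in replicate 1 and 4 that did not pass (1 adjusted over the list alone). The cluster of Mir183, Mir96 and Mir182 had a median of -0.39, with 2 higher in replicate 1 and 1 in replicate 2 (3 adjusted over the list alone). The genes that resemble other RNA classes had a median of 0.37, with 4 of 7 higher in replicate 2, 1 higher in replicate 1 and 2 that did not pass (5 adjusted over the list alone). By total counts 5 of the 7 were higher in replicate 2 and none in replicate 1. Their summed share was 2.41 times as high in replicate 2, which follows Mir1839, at 501 and 1385 CPM. Of the 12 let-7 genes, 9 were higher in replicate 1, 1 was higher in replicate 2 and 2 did not pass (10 adjusted over the list alone), at a median of -0.14. By total counts the split was 5 against 4. Of 48 tested Dlk1-Dio3 genes, 18 were higher in each library and 12 did not pass (36 adjusted over the list alone), at a median of 0.0056. By total counts, 24 were higher in replicate 2 and 11 in replicate 1. Of the 24 steroid-cell microRNAs, 12 were higher in replicate 2 and 11 in replicate 1 (24 called adjusted over the list alone), at a median of 0.041. Its summed share was 1.51 times as high in replicate 2, which follows Mir21a. The leukocyte list split 3 against 3, at a median of -0.032. Mir122 was higher in replicate 1 (log2 ratio -0.94), at 1171 and 470 counts.

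**Figure D4:**
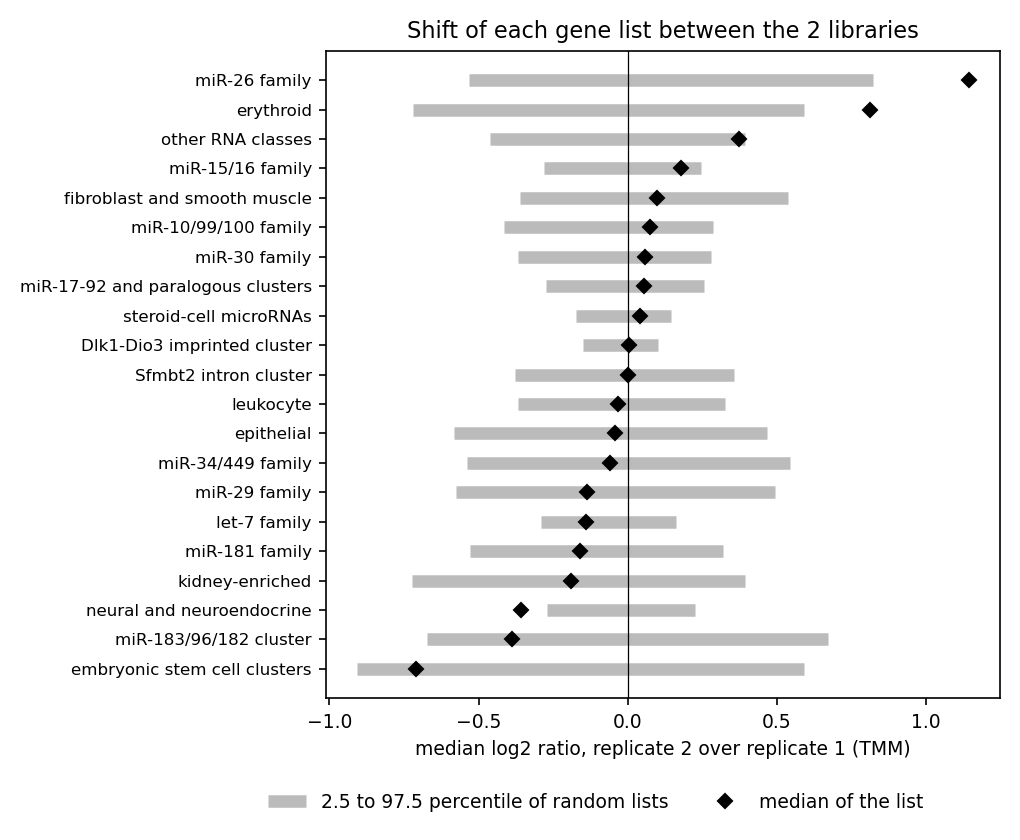
Median log2 ratio (replicate 2 over replicate 1, TMM scaling) of each list with at least 3 tested genes, as diamonds. Grey bars span the middle 95% of 10000 random lists matched on abundance. The neural and neuroendocrine list lies below its bar, and the erythroid list and the miR-26 family lie above theirs.

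Counts on the strand opposite to the gene made up 8.75% of stranded counts in replicate 1 (exact 95% interval 8.73 to 8.76) and 7.99% in replicate 2 (7.97 to 8.01). Nearly all, 99.98% and 99.97%, fell in 64 genes that overlap a microRNA gene on the other strand. The genes with the most were Mir126b, opposite Mir126a, with 563584 and 356924 antisense counts, Gm25927, opposite Mirlet7e, with 128887 and 102922, and Gm24083, opposite Mir191, with 48511 and 39901. Gm25927 and Gm24083 had no sense counts in either library. A read over such an overlapping pair counts on the strand of 1 gene and again as antisense for its partner. The antisense share is therefore mostly sense reads of partner genes counted a second time. It does not measure separate opposite-strand signal. In the counts on either strand Mir126a had 17 and 11 reads, against 563601 and 356935 on its own strand, so that column does not report its level.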

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

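The count of opposite-strand reads away from overlapping genes was chosen after the strand totals were seen. Outside the 64 genes that overlap a microRNA gene on the other strand, 216 antisense counts were left in replicate 1 and 167 in replicate 2, which is 0.00261% and 0.00278% of the stranded counts at the 2138 genes searched. Of these genes 9 in replicate 1 and 6 in replicate 2 had more than the 3 counts that a count of 0 allows for a gene. Mir708, on chromosome 7 at 96249424-96249532, had the most, with 67 and 64 antisense counts against 881 and 345 sense counts. Mir203 had 25 and 9, and Mir34b had 17 and 16. No explanation was tested.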

How the results depend on the processing

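The settings for the antisense share were chosen after its values were seen. No paired analysis was possible because the series holds 1 group. Detection rose from 403 to 674 genes at 1 count or more. A minimum fold of 1.5 left 89 of the 239 differing genes; the other settings gave 217 to 243. By total counts 211 of the 239 were called again, 10 of the 239 changed sign, and 150 of 243 were higher in replicate 2 against 110 of 239. The cause lies in the scaling itself, which moves every ratio by 0.10. It reversed named genes near 0, with Mirlet7b at 0.084, Mir10a at 0.080, Mir139 at 0.049, Mir195a at 0.049 and Mir203 at 0.021. All lists together held 72.5% of counts, 70.5% in the counts on either strand and 69.0% without Mirlet7g, and the let-7 family held 31.2%, 32.6% and 22.4%. In a single library the let-7 share was 30.4% to 31.9% and the Dlk1-Dio3 share 4.84% to 5.84%. Antisense reads fell from 8.37% to 0.0027% without overlapping genes. The coefficient of variation stayed between 0.293 and 0.302. Depth limits statements below 1.52 CPM, which is 10 counts in replicate 2.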

Other observations

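The tests of clusters, seed families, copies and opposite-strand genes were chosen after values they bear on were seen, the requirement that an interval lie below 0.5 and the run without genes that share 21 bases were added after the correlations were seen, and the GC test alone was set before its result. Genes named here outside the naming rule were chosen after their values were seen.

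Much of the counted adrenal microRNA pool came from clustered genes. Genes on the same strand with gaps of at most 10 kb formed 124 clusters of 479 genes, which held 44.7% ± 1.28 of the counts (SD, n = 2). The pair Mirlet7b and Mirlet7c-2 on chromosome 15 held 8.61% ± 0.355. The cluster of Mir23b, Mir27b and Mir24-1 on chromosome 13 held 6.13% ± 0.294, its paralogue of Mir23a, Mir27a and Mir24-2 on chromosome 8 held 4.33% ± 1.86, and Mirlet7e with Mir125a and Mir99b on chromosome 17 held 3.41% ± 0.0599. The X-linked cluster of Mir322, Mir351, Mir542 and Mir503 held 1.10% ± 0.0604, with 7 of its 7 genes detected.

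By chromosome, chromosome 11 held 13.02% ± 2.46 of the counts, chromosome 9 held 12.6% ± 0.890, and chromosome 12, with 62 detected genes, the most of any, held 5.58% ± 0.735. The X chromosome held 4.86% ± 0.223 from 36 detected genes, including Mir652 at 13536 ± 1103 CPM.

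The libraries differed at 158 of the 184 genes above 100 CPM, and neighbours in a cluster parted in some cases and not in others. In 11 of the 27 clusters with at least 2 genes above 100 CPM the ratios of the members spanned more than 2-fold. In the other 16 they did not. The bound was chosen after the ranges were seen. The 11 include Mir15a with Mir16-1, Mir30e with Mir30c-1, and Mir23b with Mir27b and Mir24-1. Mir16-1, Mir30c-1 and Mir24-1 are multi-copy genes whose counts are uncertain. Mir497 had a log2 ratio of -1.30 and Mir195a of -0.054, Mir222 of -1.22 and Mir221 of -0.14, and Mir23a of -1.04 and Mir27a of 0.11, while Mir181d and Mir181c spanned 0.014 and Mir191 and Mir425 spanned 0.020. A shared change of clustered primary transcripts is argued against as the whole source, with an intraclass correlation of 0.0454 over 92 genes in 27 clusters (bootstrap interval -0.195 to 0.177, permutation p = 0.319). A straight line on GC content of the whole hairpin removed 0.0722% of the variance. The libraries hold fragments below 30 nt, so this cannot decide on the GC content of the sequenced fragments, which was not tested. A shared shift of similar mature sequences had an intraclass correlation of 0.121 over 40 genes in 8 families (interval -0.311 to 0.265, permutation p = 0.204), below the 0.5 set for a shared shift, and -0.100 over the 25 genes that share no 21-base stretch. The cluster correlation was not computed without genes that share such a stretch, so uncertain counts enter it. What stays open, untested, is a difference between the tissue samples that acts on single mature microRNAs. A step of library preparation that may act on single sequences stays open too, also untested.

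Genes with a second copy had lower counts on average. In 7 of 7 families or groups of clusters, genes whose hairpin shares 21 bases with another microRNA locus had lower levels than the other members, by 4.52 on average in log2(CPM + 1) (one-sided permutation p = 3e-05). Copies of the same sequence carry the same label and are not independent genes, so this p-value may be too small. Mirlet7a-1 had 602 CPM and Mir26a-2 had 132 CPM, against 84252 CPM for Mirlet7b and 21281 CPM for Mir26b, but Mirlet7f-2 had 7567 CPM against 7706 CPM for the unshared Mir98, and the miR-15/16 difference was 1.14, with Mir16-1 at 910 CPM above Mir15b at 731 CPM. Leaving reads that align to more than one locus out of the counts could give this pattern. Reads with several alignments were 35.9% and 36.0% of all reads in the libraries. What part of them came from microRNA loci is not known. A lower level of these microRNAs in the tissue was not tested and stays open.

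Some abundant genes were near 0 in the counts on either strand, such as Mir126a, Mirlet7e, Mir191 and Mir30e. The counts lost against the stranded column made up 99.97% of the ambiguous reads, in the library with the lower value. This is in line with reads over genes annotated on opposite strands being counted as ambiguous. No biological explanation was tested.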
